A study of Mus musculus with 8 samples.

How the data were processed

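Open chromatin was profiled by ATAC-seq, in which the Tn5 transposase cuts accessible DNA and inserts sequencing adapters, in 8 libraries from C57Bl/6J mouse brain. The labels give 4 groups of 2 libraries: Fn14 knockout (KO), wild-type littermates (WT), PLX chow and control chow. Each aliquot held 50000 nuclei and libraries were made with a Nextera kit, per the labels' protocols. The labels spell the compound in the chow PLX5562 and say that it was given to remove microglia.

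The authors processed paired-end reads with the ENCODE ATAC-seq pipeline on genome build mm10, with multimapping set to 0 and a peak-calling p threshold of 0.01, per the deposited pipeline instructions. The names of the deposited lists record read trimming, removal of duplicates and mitochondrial reads, a Tn5 step, a limit of 300000 peaks per list and a final filter. The submitters' processing notes also name deepTools 3.5.0 without saying for which step. The aligner, the peak caller and their versions are not given in the sources used here. Peaks were called per sample and not on pooled samples. Each deposited list gives per peak a score, a fold enrichment (a ratio over the local background), a p-value and a q-value as −log10, and the position of the summit. These are the authors' own values for each peak, and they were used here only to describe, rank or filter peaks within a list. The deposited score is 10 times the −log10 p with an upper limit of 1000. No read counts were used, so the sequencing depth of each library is unknown and no counting interval can be given.

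Overlapping peaks of a library were merged into regions, each keeping its highest −log10 p, and the 50000 regions with the highest −log10 p were selected, so that every library entered with a list of 1 length. A region was called for a group when it overlapped, by 1 bp or more, a selected region in every library of that group and no deposited peak in any library of the other group. Each region was assigned by its centre to the nearest of 21883 protein-coding genes within 50 kb. The gene table (assembly GRCm38.p6, the mm10 build) carries no strand, so distance to the gene interval replaced distance to the transcription start, and "within 1 kb of a gene end" replaced "within 1 kb of a start". 13 gene lists with 319 genes in all were fixed, and all 319 matched the table by symbol. They cover microglia, endothelial and mural cells, astrocytes, oligodendrocytes, oligodendrocyte precursors, cortical and hippocampal excitatory neurons, thalamic neurons, inhibitory neurons, activity-regulated genes, TWEAK, TNF receptor and NF-kB genes, synapse genes, circadian clock genes and housekeeping genes. For each list the log2 ratio of the mean number of selected regions per library was computed after adding 0.5 to both sides. Its 2-sided p was the percentile among 10000 random gene lists (a permutation of list membership) of the same size, matched on the number of regions per gene in 20 classes. P-values were adjusted over the 13 lists of a comparison by the Benjamini-Hochberg method, and 0.0002 is the smallest p that these draws can give. Such a p compares a list with other genes in the same libraries, not mice with mice. Genes were also compared by whether the counts of their libraries overlapped between groups. By chance 33.3% of genes without ties would separate with 2 libraries against 2, and 2.86% with 4 against 4.

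Pairs of libraries were compared by the Jaccard index of their selected base pairs. A comparison of 2 libraries with 2 has 3 splits, so that its smallest exact p is 0.333 and none can pass 0.05. The 4 dLGN and 4 section libraries have 35 splits, with a smallest exact p of 0.029. The rule for named genes took Tnfrsf12a and Tnfsf12 in all comparisons, 8 microglial genes in the chow comparison and 6 regional marker genes in the tissue comparison. It added the genes assigned to the 10 strongest called regions per direction and, from each list, the 2 members with the largest difference among those whose groups did not overlap. Siglech, Hpgds, Runx1, Pik3r6 and Nfkbia, and Adarb2, Sox6 and Gad2 in the closing observations, lie outside this rule and were chosen after their values were seen. Some genes that the rule names are not reported here. The groups, tests, gene lists, naming rule and first set of alternatives were fixed before the data were examined. The alternatives were 25000 or 100000 selected regions, all deposited peaks, a q-value limit of 0.05, a looser rule for absence, an overlap of at least 50% of the shorter region, other assignments of regions to genes, the replicate number as a block and leaving out each replicate. Alternatives added after seeing the data cut every list to 192168 regions, reduced regions to 200 bp, counted regions lost per list, matched random lists on gene length too (5 classes), counted the named genes that kept their direction with 100000 regions, compared all 28 pairs of libraries, or kept only the WT and control chow libraries. Tests of sequence motifs were not run, since no genome sequence was used here. Nothing in the labels says that replicates came from separate animals, so differences between replicates may be technical. The list p-values compare genes, Fisher's exact p-values compare regions, and the exact p-values of splits compare groupings of these libraries. None of them measures the spread between mice.

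The rules were tested on simulated lists made from a real library with the noise seen between replicates. With 200 regions removed from 1 group, 83.0% were called in the Fn14 design (64940 regions), 85.0% in the chow design (59179 regions) and 77.5% in the tissue design (63050 regions). With no change the rule called 0 regions in each design. All simulated libraries shared the regions of 1 real library, with noise taken from regions found in both replicates. A selected region could thus hardly lose its peak, and the 0 gives no rate of false calls. In the real Fn14 libraries, grouping by replicate number called 12 regions and the remaining split across genotypes 25. Of 200 regions with a 4-fold or 2-fold lower −log10 p, the rule called 0 in each design, so it finds losses of a peak and not weaker peaks. Of 200 unchanged random gene lists, 5.0% had a p under 0.05 in the Fn14 design (15816 genes), 3.5% in the chow design (15258 genes) and 4.5% in the tissue design (16402 genes). With the mean number of regions of every member lowered by 25% in 1 group, 93.0%, 100% and 72.0% of 100 lists had an unadjusted p under 0.05, in the same order. Every member lost the same share and no single regions were drawn for removal. These rates may therefore be too high for real losses, which vary from gene to gene. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with 1 as the random seed.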

Results

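Accessible chromatin was mapped in 8 mouse brain libraries. Mice lacking Fn14, the receptor for the cytokine TWEAK encoded by Tnfrsf12a, and their wild-type littermates gave coronal sections at postnatal day 27 that held cortex, hippocampus and the dorsal lateral geniculate nucleus (dLGN, the visual relay of the thalamus), with 2 libraries per genotype. C57Bl/6J mice fed PLX chow or control chow from postnatal day 20 gave microdissected dLGN at postnatal day 32, with 2 libraries per diet. The deposited lists held 248989 peaks (PLX chow 1) to 299822 peaks (KO 1), which merged into 192168 (WT 1) to 218214 (KO 2) regions. The weakest of the 50000 selected regions had a −log10 p of 13.4 in WT 2 and 33.0 in control chow 1, the extremes of the 8 libraries. Between 54.9% (PLX chow 1) and 58.1% (KO 1) of selected regions had their centre inside a protein-coding gene. Read depth is unknown.

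**Figure D1:**
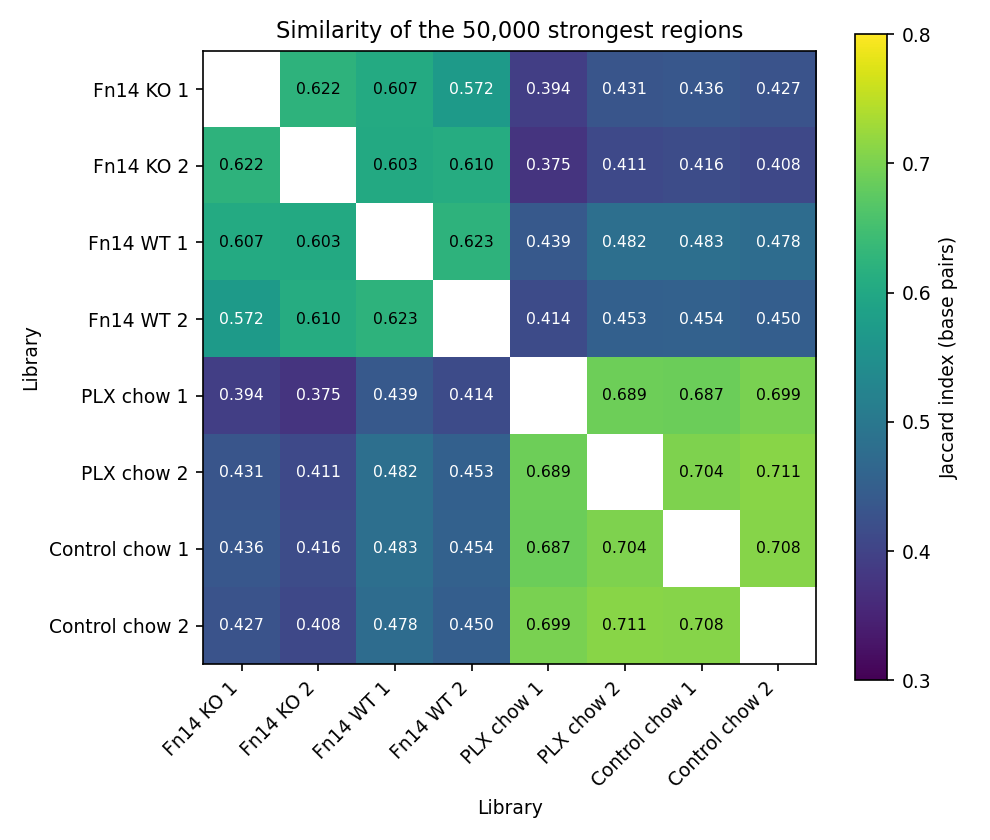
Jaccard index (shared over total base pairs) of the 50000 selected regions for each pair of the 8 libraries, with libraries on both axes and colour from 0.3 to 0.8. Pairs of dLGN libraries lie between 0.687 and 0.711, pairs of section libraries between 0.572 and 0.623, and pairs of a dLGN with a section library between 0.375 and 0.483.

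The first comparison asked how chromatin accessibility differs in brain sections without Fn14. At Tnfrsf12a (chromosome 17, 23675445 to 23677449, mm10), both WT libraries and all 4 dLGN libraries had a peak over the upper end of the gene, at 23677365 to 23677642, and neither KO library had one. The authors' −log10 p there was 13.6 in WT 1, 8.02 in WT 2, 10.0 and 19.4 in the PLX chow libraries and 24.5 and 25.3 in the control chow libraries, with folds of 2.42 to 3.56. A stronger region 1065 bp beyond the other end of the gene, at 23673184 to 23674379 over Hcfc1r1 and Thoc6, was present in all 8 libraries, with 357 and 257 in the KO libraries. At Tnfsf12, the gene of the ligand TWEAK, the region over the upper gene end (chromosome 11, 69695102 to 69696181) was found in all 8 libraries, with a −log10 p of 20.0 and 13.4 in KO and 12.5 and 6.53 in WT. None of the Tnfrsf12a and Tnfsf12 regions assigned by centre ranked among the 50000 selected in any library.

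**Figure D2:**
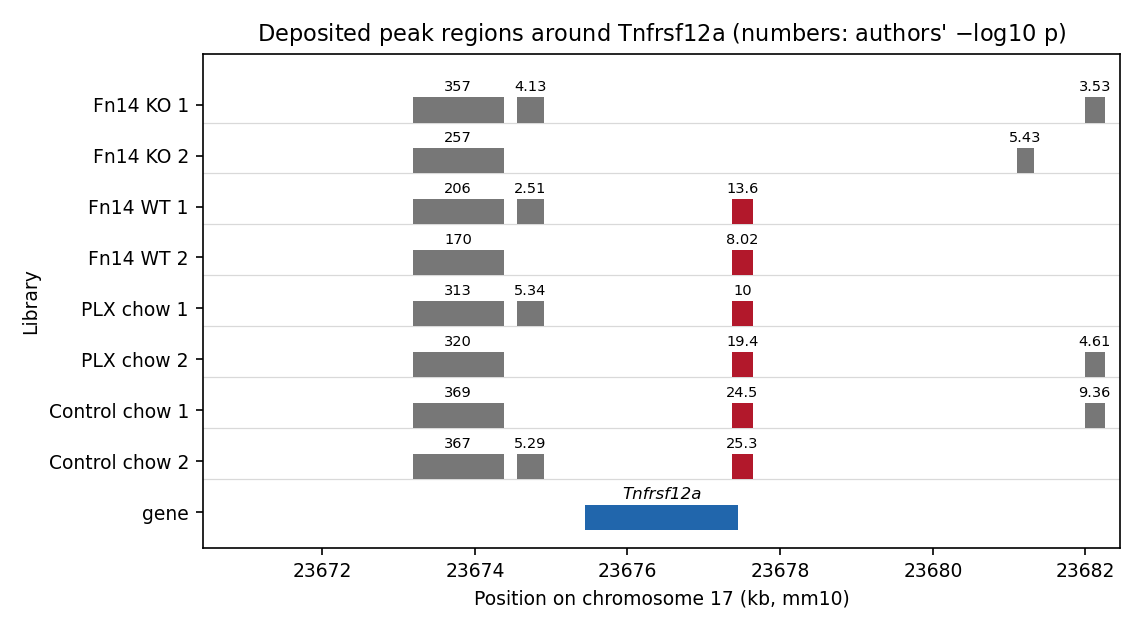
Regions with a deposited peak within 5 kb of Tnfrsf12a on chromosome 17 (horizontal axis, position in kb, mm10) in each of the 8 libraries (vertical axis), with the authors' −log10 p above each region. The region at the upper gene end (red) is present in 6 libraries, with 8.02 to 25.3, and in neither KO library.

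Regions called for 1 genotype were few. 12 regions were selected in both KO libraries with no peak in either WT library, and 4 were selected in both WT libraries with no peak in either KO library. The strongest KO-only region lay 8208 bp from Myadm (chromosome 7, 3280254 to 3281406; −log10 p 32.5 and 29.4). Others lay inside Uhrf1bp1 (chromosome 17, 27871761 to 27872261; 29.9 and 23.4), P4ha3 and Ntng2 and within 50 kb of Aldh3a1, Gm52796 and Dynlt1b. The weakest, chosen for naming after their values were seen, lay inside Pik3r6 and 2610 bp from Nfkbia, which encodes an inhibitor of NF-kB (chromosome 12, 55495143 to 55495371; 27.6 and 19.4). The WT-only regions lay inside Gm2396 and Arhgap6 (chromosome X, 168935530 to 168935763; 22.7 and 14.2), 42675 bp from Commd8, and more than 50 kb from any gene. The total of 16 was not the largest of the 3 splits of these 4 libraries, since grouping by replicate number gave 12 and the remaining split 25. Libraries of 1 genotype were slightly more alike, with a Jaccard index of 0.623 ± 0.000316 (SD, 2 pairs) within and 0.598 ± 0.0175 (SD, 4 pairs) between genotypes, a difference of 0.0244 that was the highest of the 3 signed differences (exact 1-sided permutation p = 0.333, the smallest possible). Grouping by replicate number gave 0.00334, and the crossed split gave −0.0277, which is larger in size. The difference between genotypes was 0.0159 without KO 1, 0.0155 with all deposited peaks and 0.0140 with the replicate number as a block. The selected regions covered 36.5 and 35.8 Mb in the KO libraries and 32.9 and 33.5 Mb in the WT libraries. An index of base pairs has a lower ceiling between lists of unequal cover, and how much of the difference comes from this was not tested.

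By gene list, astrocyte genes had 79.5 ± 7.78 selected regions per library in KO and 94.5 ± 2.12 in WT (SD, n = 2 each), and 0 members had more regions in both KO libraries while 3 had fewer. Slc4a4, a bicarbonate transporter, had 14.5 ± 2.12 and 21.5 ± 0.71 regions, and Aqp4, the water channel of astrocyte endfeet, 2.5 ± 0.71 and 4 ± 0. Inhibitory neuron genes had 54.0 ± 9.90 in KO and 63 ± 0 in WT, with 1 member higher and 4 lower, among them Erbb4 (5.5 ± 2.12 and 10.5 ± 2.12) and Reln (8 ± 2.83 and 11 ± 0). Microglial genes had 75 ± 0 in KO and 63.0 ± 1.41 in WT, with 6 members higher and 1 lower, among them Inpp5d (6 ± 0 and 2.5 ± 0.71) and the fructose transporter gene Slc2a5 (3 ± 0 and 0.5 ± 0.71). None of the 13 lists passed the permutation test against random lists after Benjamini-Hochberg adjustment, and 3 had an unadjusted p under 0.05. These were astrocyte (log2 ratio −0.25, permutation p = 0.0072, adjusted 0.094), inhibitory neuron (−0.22, p = 0.034, adjusted 0.17) and microglia (0.25, p = 0.040, adjusted 0.17). KO 1 had only 47 inhibitory neuron regions against 61 to 63 in the other section libraries, and without it the log2 ratio was −0.05 (adjusted permutation p = 0.92) while the oligodendrocyte list passed (−0.35, adjusted 0.023). Without KO 2 the astrocyte (−0.35) and inhibitory neuron (−0.42) lists passed, each with an adjusted permutation p of 0.018. With 25000 selected regions the astrocyte (−0.40), microglia (0.49), oligodendrocyte precursor (−0.44) and thalamic neuron (−0.53) lists passed, with adjusted permutation p of 0.0078, 0.0078, 0.031 and 0.0078.

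Among activity-regulated genes, 5 members had more regions in both KO libraries and 1 had fewer, with a list ratio of 0.08 (adjusted permutation p = 0.67). The immediate early gene Fos had 11 ± 0 selected regions in KO and 5.5 ± 0.71 in WT, and Dusp1 had 3.5 ± 0.71 and 1.5 ± 0.71. Synapse genes split 5 higher and 3 lower (list ratio 0.02), with Grin2a, an NMDA receptor subunit, at 9 ± 5.66 and 2.5 ± 2.12 and the scaffold gene Shank2 at 12.5 ± 2.12 and 6.5 ± 0.71. TWEAK, TNF receptor and NF-kB genes had 55.5 ± 0.71 regions in both genotypes (ratio 0), with 0 members higher and 2 lower, Map3k7 at 3.5 ± 0.71 and 6.5 ± 2.12 and Traf5 at 3 ± 0 and 4 ± 0. The thalamic neuron list (−0.11) had 0 members higher and 3 lower, with Foxp2 at 4 ± 1.41 and 7.5 ± 0.71, and WT 1 held 84 regions of this list against 72 to 73 in the other section libraries. Cortical and hippocampal excitatory genes (0.01) had 2 higher and 3 lower, with Bcl11b at 8.5 ± 0.71 and 5 ± 1.41 and Zbtb20 at 15 ± 0 and 19 ± 2.83. The remaining log2 ratios were −0.16 for oligodendrocyte, −0.18 for oligodendrocyte precursor, −0.07 for endothelial and mural, 0.04 for circadian clock and 0.11 for housekeeping genes. Over 16402 genes with a selected region in any library, 1272 (7.76%) had more in both KO libraries and 952 (5.80%) fewer. The 33.3% that chance gives holds only for genes without ties, while these shares count every gene, so the values cannot be compared directly. With 100000 selected regions, 18 of the 26 genes that the naming rule took from the lists kept their direction, 5 tied and 3 turned. Among them Reln (19 in KO and 18.5 in WT) and Map3k7 (14.5 and 13) turned, Traf5 tied at 6, and the differences at Fos (11.5 and 11), Inpp5d (12 and 11), Grin2a (25.5 and 15.5) and Slc2a5 (4 and 2) became smaller as ratios. At the deposited threshold Fos had 0 KO-only and 2 WT-only regions.

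The second comparison asked how chromatin in the dLGN differs under a diet given to remove microglia. At Csf1r, the receptor gene on which microglial survival depends, the region at 61108359 to 61109129 on chromosome 18, inside the gene, had a −log10 p of 13.1 and 13.8 in the control chow libraries and no peak in either PLX library. At P2ry12, a purinergic receptor gene used as a marker of resting microglia, 4 regions inside the gene, which lies within Med12l, were present in both control libraries and absent from both PLX libraries, the strongest on chromosome 3 at 59234978 to 59235206 (16.4 and 16.6). That region also had no peak in either KO library, while the other 3 had a peak in all 4 section libraries. Another region inside Csf1r, with a higher −log10 p, and 1 inside Cx3cr1 kept a peak in both PLX libraries (see the closing observations). Of the 212 regions at microglial genes with a peak in both control libraries, 24 (11.3%), at 15 genes, had no peak in either PLX library. The median of matched random lists was 5.48% (permutation p = 0.0022, adjusted 0.029 over the 13 lists). With all libraries kept, no other list had an adjusted p under 0.05. Siglech, Hpgds and Runx1 had 3 such regions each, all named after their values were seen, and Trem2, Spi1 and Sall1 had 1 each. All 24 were weaker than the weakest selected region of control chow 1 (33.0) and control chow 2 (27.1). Several lay near the peak-calling threshold. In control chow 2 the −log10 p was 3.47 at Trem2, 3.08 at Spi1 and 2.04 at 1 region each of Hpgds and Fcgr1. The Sall1 region lay 19435 bp and the Fcgr1 region 38920 bp from the gene. Absence of such weak peaks is not a clear loss of a strong peak. In the other direction, 6 of 182 regions at microglial genes (3.30%) were found in both PLX libraries and in neither control library, against a median of 2.96% for random lists.

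This test of lost regions was chosen after the planned test had been seen, and the planned test did not pass. Microglial genes had 73.5 ± 0.71 selected regions per library in PLX and 78.0 ± 4.24 in control chow (SD, n = 2 each), with 0 members higher and 1 lower. Their log2 ratio was −0.09 (permutation p = 0.20, adjusted 0.72). Of 9 statistics computed for this list, 8 were added, of which 6 had an adjusted p under 0.05. Without control chow 2 the loss was 22.6% against a random median of 18.3%, and without PLX chow 2 it was 18.7% against 12.0%. The list no longer passed the adjusted threshold in either case. Leaving out a library also loosens the rule, which raised both the loss and the random median. These runs show that passing depends on the libraries kept, but not which library carries the loss. Without control chow 1 another list passed beside the microglial one, and without control chow 2 another passed in its place. With 100000 selected regions the loss was 1.69%, 2 of 118 regions, against a random median of 0% (permutation p = 0.019, adjusted 0.25).

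**Figure D3:**
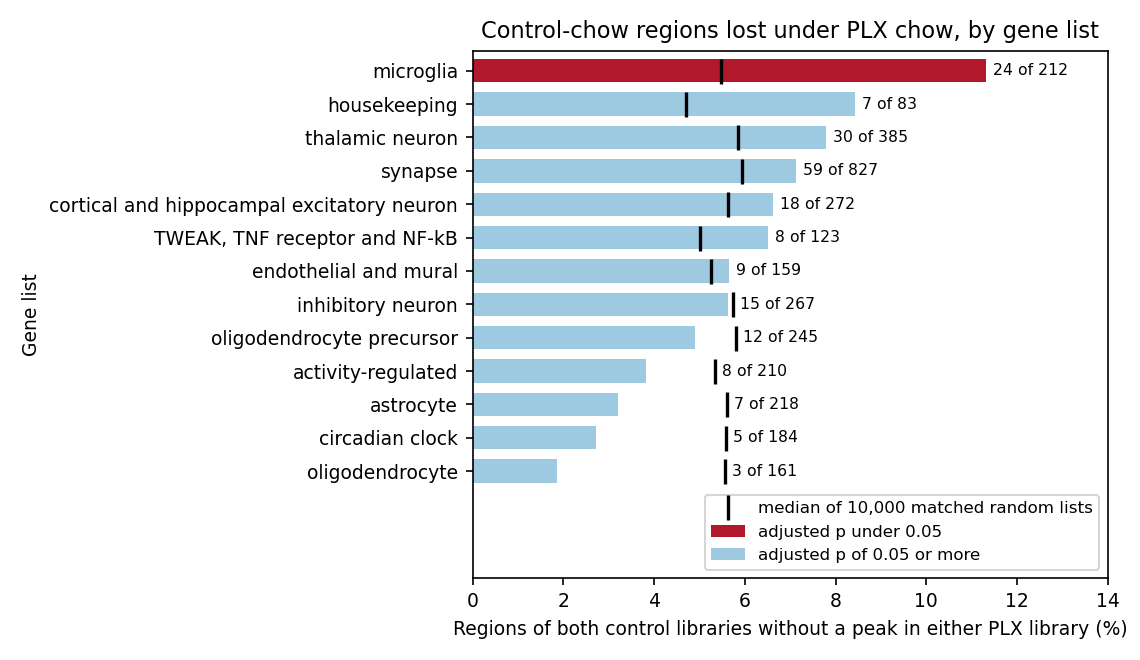
Percentage of regions present in both control chow libraries that had no deposited peak in either PLX library (horizontal axis), for each of the 13 gene lists (vertical axis), with counts beside the bars and the median of 10000 matched random lists as a black mark. Microglial genes (24 of 212, 11.3%) lie farthest above their random median of 5.48%.

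Among selected regions the diets differed little. A single region was called for PLX chow (chromosome X, 50605540 to 50605875, more than 50 kb from any gene; −log10 p 27.9 and 32.2) and 0 for control chow, and both other splits of the 4 libraries gave 0. The Jaccard index within diets was 0.699 ± 0.0137 (SD, 2 pairs), and its difference from pairs between diets was −0.00192. The other 2 splits gave −0.00076 and 0.0027, so that all 3 were at least as high. Of the 13 lists, 0 passed the permutation test against random lists and 0 had an unadjusted p under 0.05. Of the genes named in advance, the following counts were found. P2ry12 had 2 ± 0 selected regions in PLX and 3 ± 1.41 in control chow, Spi1 1 ± 1.41 and 2 ± 0, Sall1 2 ± 0 and 2.5 ± 0.71, and Trem2 1 ± 0 in both. Csf1r, Cx3cr1 and Tmem119 had 0 in every library of both diets. Apbb1ip had 5 ± 0 in PLX and 6 ± 0 in control chow. Oligodendrocyte genes (log2 ratio 0.04) had 2 members higher and 0 lower in PLX, among the former Ugt8a at 9.5 ± 0.71 and 7.5 ± 0.71. Astrocyte genes (0.03) had 2 higher and 1 lower, the glutamate transporter gene Slc1a3 at 11 ± 1.41 and 13.5 ± 0.71 and Acsbg1 at 2.5 ± 0.71 and 1 ± 0. Synapse genes (−0.01) had 1 higher and 2 lower, among the latter Grin1 at 0 ± 0 and 1 ± 0. Inhibitory neuron genes (−0.01) had 1 higher, Gad1 at 2 ± 0 and 1 ± 0, and 2 lower, among them Pvalb at 0 ± 0 and 1.5 ± 0.71. Activity-regulated genes (−0.04) had 0 higher and 2 lower, Atf3 at 3 ± 0 and 4 ± 0 and Nr4a1 at 4 ± 0 and 5 ± 0. The remaining log2 ratios were −0.06 for endothelial and mural, 0.06 for oligodendrocyte precursor, −0.06 for cortical and hippocampal excitatory, −0.02 for thalamic neuron, 0.04 for TWEAK, TNF receptor and NF-kB, 0.06 for circadian clock and −0.10 for housekeeping genes. Over all 16402 genes, 518 (3.16%) had more regions in both PLX libraries and 523 (3.19%) fewer. Genes with ties are counted here too, so the 33.3% by chance without ties is no direct comparison. With 100000 selected regions, 12 of the 22 genes taken from the lists kept their direction, 6 tied and 4 turned. Among these Nr4a1 tied at 5 and Pvalb turned (3 in PLX and 2.5 in control chow), as did Spi1 of the genes named in advance (2.5 and 2), while Acsbg1 (7 and 5.5), Gad1 (6.5 and 5) and Grin1 (1 and 2) kept theirs. With all deposited peaks, microglial genes (log2 ratio −0.14) and circadian clock genes (0.14) passed, each with an adjusted permutation p of 0.042.

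The 4 dLGN libraries were also set against the 4 section libraries, which differ in tissue, in age and possibly in preparation, so these cannot be told apart. The dLGN side also includes the 2 PLX chow libraries and the section side the 2 Fn14 KO libraries. Foxp2, a transcription factor gene of thalamic neurons, had 13.8 ± 2.22 selected regions per dLGN library and 5.75 ± 2.22 per section library (SD, n = 4 each). Genes were taken from the lists only where the libraries of the tissues did not overlap, so no p-value is given for them. The markers Tcf7l2 (3.75 ± 0.96 and 5.25 ± 0.50), Lef1 (4 ± 0 and 3.5 ± 1.29), Gbx2 (0.5 ± 0.58 and 0 ± 0) and Neurod6 (4.5 ± 1.29 and 3 ± 0) overlapped between tissues, and all 8 libraries had 0 selected regions assigned to Tnfrsf12a and Tnfsf12.

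Called regions separated the tissues. 950 regions were selected in all 4 dLGN libraries with no peak in any section library, and 1725 the other way round. The centre lay inside a gene for 28.4% of dLGN-only and 40.6% of section-only regions. The strongest dLGN-only region (chromosome 10, 114106709 to 114107258) had a −log10 p of 156 to 218 and no gene within 50 kb, and the strongest inside genes lay in Spata17 (chromosome 1, 187043008 to 187043837; 101 to 135), Ctnna3 (chromosome 10, 64820173 to 64820605; 96.4 to 174) and Pkhd1l1 (chromosome 15, 44493476 to 44493941; 94.9 to 134). The strongest section-only region (chromosome 10, 51271235 to 51271994) had 112 to 141 and no gene within 50 kb. Clvs2 held the strongest section-only region inside a gene (chromosome 10, 33540334 to 33540858; 90.7 to 145), and another lay 3715 bp from the olfactory receptor gene Olfr994 (chromosome 2, 85425768 to 85426568; 81.8 to 96.6). Ctnna3 had 3 dLGN-only and 5 section-only regions.

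Activity-regulated genes had 91.8 ± 3.30 selected regions per dLGN library and 113.8 ± 3.86 per section library, with 1 member higher in dLGN and 4 lower. Nrn1 had 2 ± 0.82 and 6.25 ± 0.96 regions and Jun 5 ± 0 and 2.5 ± 0.58. Synapse genes had 201.8 ± 8.77 and 237.0 ± 10.4, with 1 member higher and 6 lower, among them the NMDA receptor gene Grin2b (8.25 ± 0.96 and 13.2 ± 1.89). Both lists had an unadjusted permutation p under 0.05 (log2 ratios −0.31, p = 0.024, and −0.23, p = 0.014), and 0 of the 13 passed after Benjamini-Hochberg adjustment (both adjusted 0.15). Inhibitory neuron genes (log2 ratio 0.26, adjusted permutation p = 0.30) had 3 members higher in dLGN and 1 lower, with Erbb4 at 14.8 ± 1.26 and 8 ± 3.37 and Npy at 2.75 ± 0.50 and 0.75 ± 0.50. Thalamic neuron genes (0.19, adjusted 0.34) had 5 members higher and 1 lower, the latter Rora at 6.75 ± 2.22 and 12 ± 2.71. Microglial genes (0.13) had 3 higher and 0 lower, with Dock2 at 16 ± 1.63 and 7.25 ± 0.96 and Ptprc at 8.25 ± 0.96 and 4.75 ± 0.96. Endothelial and mural genes (0.22) had 5 higher and 1 lower, with the pericyte gene Rgs5 at 3 ± 0 and 0.75 ± 0.50. Astrocyte genes (−0.17) had 0 higher and 3 lower, with Fgfr3 at 0.75 ± 0.50 and 3 ± 0.82. Cortical and hippocampal excitatory genes (−0.13) had 3 higher and 3 lower, with Satb1 at 6.25 ± 0.50 and 2.5 ± 0.58. The remaining log2 ratios were 0.18 for oligodendrocyte, 0.14 for oligodendrocyte precursor, −0.11 for TWEAK, TNF receptor and NF-kB, −0.12 for circadian clock and −0.22 for housekeeping genes. Over 16402 genes, 1075 (6.55%) had more regions in every dLGN library than in any section library and 1169 (7.13%) fewer. The 2.86% by chance for both directions together holds only for genes without ties, while ties are counted here, so it is no direct comparison. Both directions together gave 2244 genes, and the highest other split of the 8 libraries gave 125. With 100000 selected regions, 21 of the 23 genes taken from the lists kept their direction and 2 turned, among the latter Fgfr3 (5.5 in dLGN and 5.25 in sections). The marker Tcf7l2 also turned (18.2 and 17.5), and the ratios of Foxp2 (25.2 and 16.8), Nrn1 (5.75 and 8.75), Satb1 (12 and 9.75), Npy (6.5 and 4), Ptprc (10 and 8.75) and Rgs5 (4.75 and 3.75) came nearer to 1. With all deposited peaks 5 lists passed, synapse (−0.38), cortical and hippocampal excitatory (−0.33), oligodendrocyte precursor (0.31), inhibitory neuron (0.31) and thalamic neuron (0.19), with adjusted permutation p of 0.0026 to 0.040.

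**Figure D4:**
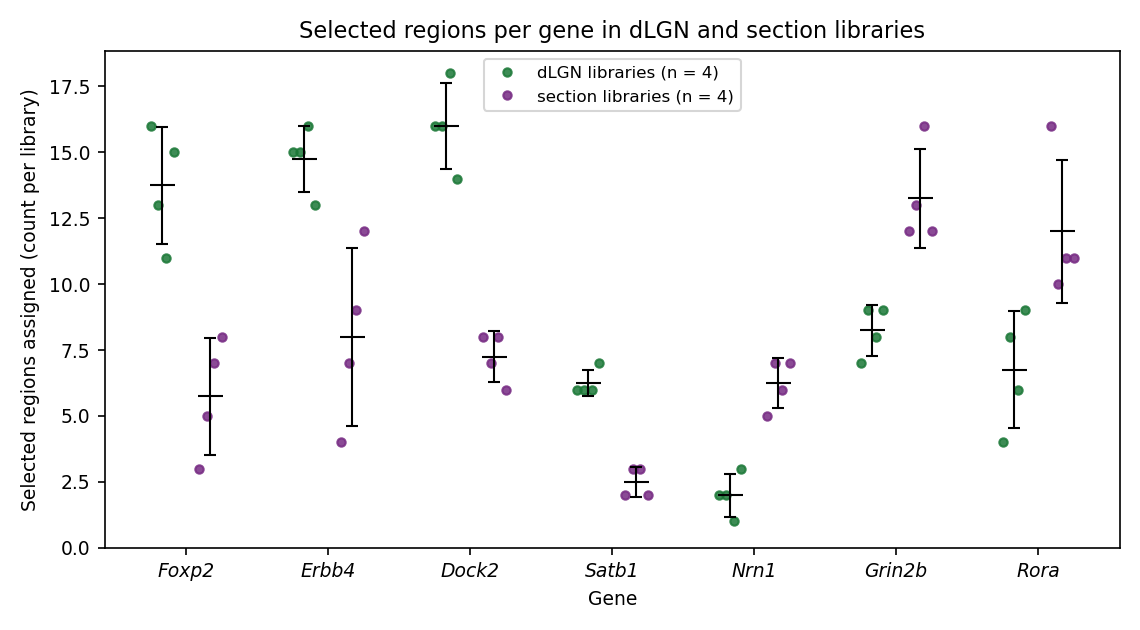
Selected regions assigned to genes named in the text (vertical axis, count per library) in the 4 dLGN (green) and 4 section (purple) libraries, with mean and SD in black. Foxp2, Erbb4, Dock2 and Satb1 lie higher in dLGN (Foxp2 13.8 and 5.75), and Nrn1, Grin2b and Rora lie higher in sections.

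The called regions of the genotype and diet comparisons were intersected, to ask whether both concerned the same regions. None of the 12 KO-only and 4 WT-only regions overlapped the PLX-only region, with 0.00017 and 5.6e-05 overlaps expected for independent lists (Fisher's exact test, p = 1 for both), so that the overlap could not be tested with so few regions.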

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

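The tests of list length, of the genotype labels and of the called regions and gene lists over splits of the 8 libraries were chosen only after the results were seen, and so was every statistic of lost regions at microglial genes. KO 1 had 47 selected regions at inhibitory neuron genes, far below the 61 to 63 of the other 3 section libraries. WT 1 had 84 at thalamic neuron genes, far above the 72 to 73 of the other 3. Of 46 sets of 4 libraries examined in this way 2 stood out, and chance marks about 1 in 20.

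At microglial genes more regions of the control chow libraries were missing from both PLX libraries than at other genes. List length does not account for it, since with lists of 1 length the odds ratio was 2.47 (Fisher's exact test, adjusted p = 0.0056). Region density and gene size stay open, since random lists matched on regions per gene, or also on gene length, each gave an adjusted permutation p of 0.029 with all libraries but 0.46 and 0.49 without control chow 2 and 0.057 and 0.053 without PLX chow 2, which the bound first set for density had left out. Loss of microglia is a candidate explanation, since among regions present in all 6 other libraries the odds ratio of absence from both PLX libraries was 5.49 (10 of 106 regions at 7 genes, exact adjusted p = 0.00042), above the 1.70 of the next list, although regions are not independent replicates and other differences between the diets were not tested. Chance cannot be excluded on the odds ratio, because 2 of the 28 pairs of libraries had an odds ratio as large, the other being KO 1 with PLX chow 2 at 5.89, which rests on 1 region, while by Fisher's exact p, a ranking chosen after the result was seen, the PLX pair came first of the 28 (3.2e-05, the next smallest being 0.16).

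The peak at the upper end of Tnfrsf12a was missing from both KO libraries. Of the 1000 regions of nearest mean −log10 p with a peak in the 6 other libraries, 2% lacked one in both KO libraries. That mean was raised by the dLGN libraries (10.0 to 25.3), while the peak had 13.6 and 8.02 in the WT sections. The share over all such regions was also 2%, so a weak section peak missed by chance stays open. A library with the other genotype's label stays open, since the pattern itself fixes the number of libraries against their label here at 0. The genetic change in the KO mice is a candidate explanation, as a hypothesis, since the extent of the deletion was not analysed here. The pattern alone does not single out this gene, as 1586 of 79105 regions showed it and 1726 regions were missing from the WT pair in the same way.

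At the deposited threshold 15324 regions were KO-only and 5266 WT-only. With lists of 1 length the ratio of KO-only to WT-only regions was 1.59, with 1.11 as the highest of the other splits, so unequal length is not its whole source. With regions also reduced to 200 bp the ratio was 1.35, with 1.12 as the highest other, so wider KO regions, with a median of 308 and 296 bp over the deposited lists against 281 and 283 bp in WT, are not its whole source either. With 3 splits no share under 0.05 can be reached. Genotype stays possible, as do differences in depth, which these lists do not show.

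Between the tissues, 1 of the 35 splits of the 8 libraries gave as many called regions as the real split, with 2675 in the real split and 1 in the highest other, so a chance split of the libraries can be excluded for that count. Genes whose libraries separated numbered 2244, with 125 in the highest other split, and again 1 of 35 splits gave as many. For gene lists the real split gave 0 past the adjusted threshold and the highest other 2, so that 35 of 35 splits gave as many, which any split must at a count of 0 and which says nothing about chance.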

How the results depend on the processing

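The lists of 1 length, the counts of lost regions, the direction of named genes with 100000 regions and the comparison limited to WT and control chow libraries were chosen after seeing the data. Counts of called regions are given as KO-only, WT-only, PLX-only, control-only, dLGN-only and section-only. With 25000 selected regions they were 0, 0, 0, 0, 111 and 281. With 100000 they were 954, 282, 68, 141, 5354 and 6644. With all deposited peaks they were 15324, 5266, 4716, 8721, 19941 and 18805. With a q-value limit of 0.05 they were 13272, 3598, 3506, 6732, 18082 and 16951. With absence meaning not selected they were 2603, 2238, 983, 1010, 8120 and 5806. With lists of 1 length the first 4 were 10957, 6890, 5687 and 6487. Only WT and control chow libraries gave 1979 dLGN-only and 2784 section-only regions. The direction of dLGN-only against section-only turned with all deposited peaks, the q-value limit and the looser absence, and that of PLX-only against control-only with 100000 regions, all deposited peaks, the q-value limit, the looser absence, lists of 1 length and without control chow 1 (1 PLX-only and 3 control-only), while with 25000 regions both genotypes tied at 0, as did both diets. The cause of these changes was not tested. An overlap of at least 50% of the shorter region moved no count by 1.5 times.

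Leaving out 1 library in turn, which loosens the rule, gave 67 to 151 KO-only, 22 to 46 WT-only, 1 to 4 PLX-only, 1 to 3 control-only, 983 to 1422 dLGN-only and 1816 to 2220 section-only regions. Regions shared in direction by the Fn14 and chow comparisons numbered 1 with 100000 regions, 218 with all peaks, 145 with the q-value limit and 36 with the looser absence. With all peaks every combination of directions overlapped less than independent lists would. The background held regions selected in more than 1 library of either comparison. A region found in only 1 of the tissues counts in it but cannot be called in both comparisons. A deficit is therefore partly built in, and these values do not show that genotype and diet regions avoid each other. KO-only regions overlapped 96 PLX-only (255 expected) and 245 control-only regions (471 expected), and WT-only regions 41 (86.4) and 122 (159), with Fisher's exact p of 1.2e-31, 1.7e-32, 5.0e-08 and 0.0020 over regions that are not independent.

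Lists past the adjusted threshold between genotypes numbered 4 with 25000 regions, 1 with 100000 (inhibitory neuron), 2 within genes or 5 kb (astrocyte and inhibitory neuron) and 0 to 2 without 1 library (oligodendrocyte without KO 1, astrocyte and inhibitory neuron without KO 2). Between diets they numbered 2 with all peaks or the q-value limit and 1 for lost regions, with deposited or equal lengths and all libraries kept. Other lists passed for lost regions without control chow 1 or without control chow 2. Between tissues they numbered 2 with 100000 regions, 5 with all peaks or the q-value limit and 2 within 1 kb of a gene end (thalamic and inhibitory neuron). The cause was not tested. The loss at microglial genes was 11.3% against a random median of 5.48%, and with 100000 regions it was 1.69% against 0%, no longer past the adjusted threshold (permutation p = 0.019, adjusted 0.25). Both the loss and the random median were lower there, and 2 lost regions are too few to say whether the excess shrank. Without 1 library the loss ranged from 17.5% to 26.3%, with adjusted permutation p of 0.031 to 0.46, the highest without control chow 2 (22.6%) and next without PLX chow 2 (18.7%, 0.057). The similarity difference between genotypes ranged from 0.0159 (without KO 1) to 0.0333 (without KO 2) without 1 library and was 0.0155 with all deposited peaks. Between diets it ranged from −0.016 (without control chow 1) to 0.015 (without PLX chow 2), and it was also above 0 without PLX chow 1 (0.00055), with all deposited peaks (0.0013) and with the q-value limit (0.0011). Of the results that answer a comparison, 86 values under alternatives stayed within these criteria, 69 moved and 3 became weaker. Values of similarity stayed by being closer than the spread between pairs of libraries. The log2 ratio of microglial genes between diets kept its side of the threshold in 10 alternatives and passed it in 2, all deposited peaks and the q-value limit. Of the genes taken from the lists, 18 of 26 between genotypes, 12 of 22 between diets and 21 of 23 between tissues kept their direction with 100000 regions.

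Replicate numbers are shared by the labels only as numbers. The correlation of deviations of same-numbered libraries was 0.10 in the Fn14 and −0.002 in the chow libraries, over 2 pairs each, so the numbers were not taken to pair samples. With the replicate block the similarity differences were 0.0140 and −0.00077, and 0 lists passed in each comparison, as without it. Motif tests were not run. Depth is unknown, and the lists cannot show a change in the strength of a peak.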

Other observations

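All tests in this part were chosen only after the data were seen. Inhibitory neuron genes stood out among regions that both KO libraries lacked. Of 108 such regions with a peak in all 6 other libraries, 7 (6.48%) had none in either KO library, against 1.68% at other genes (odds ratio 4.06, Fisher's exact test, adjusted p = 0.032 over 13 lists). They lay at Reln and Adarb2, with 2 each, and at Sox6, Erbb4 and Gad2, the last encoding an enzyme of GABA synthesis. The Gad2 region lay inside the gene on chromosome 2 at 22634791 to 22635064. The pair of KO 2 and WT 1 lacked 7 of 107 (6.54%, Fisher's exact test, adjusted p = 0.034), so the excess was not limited to the genotype split. The KO pair ranked only 4th of the 28 pairs of libraries for this list, and against matched random lists the share of WT regions lost (15 of 172, 8.72%) had an adjusted permutation p of 0.086.

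Synapse genes held many KO-only regions at the deposited threshold, 163 or 15.1% of those present in both KO libraries, against 10.4% at other genes (odds ratio 1.53, Fisher's exact test, adjusted p = 2.5e-05). Grouping the same 4 libraries by replicate number gave 1.63 (Fisher's exact test, adjusted p = 5.2e-05), so this excess was not limited to the genotype split. Against matched random lists its adjusted permutation p was 0.51.

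At Cx3cr1, the fractalkine receptor gene of microglia, the region at the upper gene end (chromosome 9, 120068184 to 120068474) had a peak in all 4 section libraries, with a −log10 p of 3.69 to 6.04, and in no dLGN library of either diet. A region inside the gene at 120054511 to 120055602 was found in all 8 libraries, PLX chow included, with 12.7 and 25.2 in the PLX libraries and 11.2 and 16.6 in control chow. Within Csf1r, the region at 61127369 to 61128171 on chromosome 18 was likewise kept in both PLX libraries, with 23.7 and 24.4 against 22.1 and 23.7 in control chow.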
